A study of Mus musculus with 2 samples.

How the data were processed

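Total RNA from microvesicles of 3T3-L1 adipocytes was profiled on 1-colour Agilent mouse miRNA arrays, 1 array for each of 2 time windows. Per the labels' protocols, cells in medium with 10% fetal calf serum were induced with insulin (10 µg/ml), dexamethasone (0.25 µM) and 3-isobutyl-1-methylxanthine (0.5 mM). Per the same protocols, vesicles were prepared by ultracentrifugation of 48 h conditioned medium, RNA was extracted with Trizol, and 100 ng was dephosphorylated and labelled with Cy3. The windows were named from the labels as day 2-4 and day 8-10.

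The deposited values are spot intensities on a linear scale, made per the file headers with Agilent Feature Extraction 9.5.3.1. Per the file headers, the processed intensity is the spot signal after subtraction of a fitted spatial background surface, with no normalization between arrays, so dim spots can be negative. Other deposited values are the raw intensity of each spot and its local background, a gene signal summed by the software, and flags for spots well above background, saturated spots and outlier spots. The series value table was checked against the scanner files and held the same processed intensity for 24986 of 24986 spots, so it was linear and not centred. Its medians were 0.516 at day 2-4 and 0.646 at day 8-10. The genome build of the positions in the files is not given in the sources used here. Only 21 of the 559 miRNAs with a position lay inside a miRNA gene of GRCm38.p6, so the RefSeq names table of that assembly was used only for gene names and for the genes that contain each miRNA.

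Each array held 12493 spots, among them 11340 spots of 1672 probes for 567 mouse miRNAs, spots for 10 viral miRNAs and 953 control spots. Control spots and 237 (day 2-4) or 249 (day 8-10) outlier spots were left out. A probe was detected where more than 0.5 of its remaining spots were well above background, and a miRNA where at least 1 probe was. Spots well above background made up 22.9% at day 2-4 and 24.3% at day 8-10. Because most probes were not detected, each array was scaled to the 75th percentile over the 279 probes detected on both arrays (108 and 95.2 in intensity units). Values were then set to no lower than the array's lowest detected probe (4.86 and 5.55 in intensity units) and log2 transformed. Spots were averaged per probe, and a miRNA's value was the mean over its probes detected on at least 1 array, so a probe detected on 1 array only enters at the floor on the other. Of the 121 miRNAs detected on both arrays with several probes in use, 13 had probes that moved in opposite directions.

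With 1 array per window no statistical test was possible. A miRNA was counted as higher or lower when it was detected on both arrays, differed by at least 2-fold and differed by more than 2 standard errors over spots. miRNAs detected on 1 array were given only a lower bound of the fold, and none where the bound did not pass 1. The lists were miRNAs that rise in or promote adipogenesis, those that fall in or repress it, the let-7, miR-17-92, miR-15/16, miR-29 and miR-23/27/24 groups, the Dlk1-Dio3 and Sfmbt2 clusters, marker lists for fibroblast and mesenchymal, muscle, liver and pancreas, neural, blood, endothelial, epithelial and pluripotent cells, and GC-rich or fragment entries. For each list with at least 3 detected members, the median difference was placed among 10000 random lists matched in 10 bins of mean signal. All 18 lists, the thresholds and most alternatives were fixed before the data were examined. The named miRNAs were chosen by a rule fixed then too: up to 8 largest gains and 8 largest losses, up to 4 largest bounds on each side, every detected member of both adipogenesis lists and of let-7, up to 4 members of each other list with the largest differences, and the 10 brightest entries in name order.

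The calculation was tested on simulated arrays of the same 567 miRNAs. Of 13 miRNAs changed 3-fold, 12 were counted in the right direction, and of 14 changed 4-fold, 10 were, while the remaining 4 were detected on 1 array only, in the right direction. Over changed miRNAs still detected on both arrays, a restriction added after the first run of the simulation, the median estimate was 1.38 for a true log2 change of 1.58 and 1.77 for a true change of 2. The changed miRNAs had moved the 75th percentile itself, so the 122 unchanged miRNAs shifted by -0.19, and once this shift was removed the median error was -0.020 for raised and -0.0035 for lowered miRNAs. None of 13 miRNAs changed 1.5-fold passed the 2-fold rule, and no unchanged miRNA was counted. The simulation held noise between spots only, so it could not show how often variation between arrays or preparations gives a false count. For lists of 9 members, 5 of 100 unshifted lists fell outside the central 95% of random lists, and 82 of 100 lists shifted by 1 on the log2 scale fell above it. The unshifted lists came from the same miRNAs as the random lists, so their share was largely fixed in advance.

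Alternatives covered other scalings, quantile normalization, normexp background correction with an offset of 50, the software's gene signal, the brightest probe, outlier spots, detection rules, thresholds of 1.5-fold and 3-fold, 4 standard errors, and changes to list membership. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.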

Results

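The study profiled microRNAs (miRNAs, small RNAs that repress messenger RNAs) carried by adipocyte-derived microvesicles, the membrane vesicles that 3T3-L1 adipocytes release into their culture medium. 3T3-L1 is a mouse preadipocyte line that turns into lipid-laden adipocytes after hormonal induction. Vesicles were collected from medium conditioned over 48 h, either from day 2 to day 4 or from day 8 to day 10. The cells were kept in medium with 10% fetal calf serum. No value here separates RNA of the serum from RNA of the cells, so part of the signal may come from serum. Each time window was represented by 1 array, so no difference below has a replicate check and none carries a p-value. The number of arrays limits the precision, and the standard errors given are those between spots of an array, which are technical only. Both arrays lay on 1 slide and were scanned once, and preparation, hybridisation and time window cannot be told apart. Of the 567 mouse miRNAs on the array, 156 (27.5%) were detected in day 2-4 vesicles and 166 (29.3%) in day 8-10 vesicles. No spot was saturated on either array.

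Most of the vesicle miRNA profile was shared by the early and the late preparation. Of the 145 miRNAs detected on both arrays, 111 (76.6%) differed by less than 2-fold, 23 were at least 2-fold higher at day 8-10 and 11 were at least 2-fold lower. Across the miRNAs detected on both arrays, which are not independent replicates, the log2 signals had a Pearson correlation of 0.880 and a Spearman correlation of 0.852. Each correlation runs over different probes, whose signals are not amounts, so it does not measure how much of the cargo was shared. The brightest entries, in name order, were let-7c, miR-1224, miR-199b, miR-22, miR-451, miR-494, miR-574-5p, miR-689, miR-709 and miR-720. Among them miR-709 was 1.41-fold higher at day 8-10 and miR-689 1.93-fold lower, both less than 2-fold, and the sign of miR-709 turned with the 75th percentile taken over all probes. The number of miRNAs on each side depended on the scaling: with the 75th percentile taken over all probes, 10 were higher and 29 lower. With normexp background correction, which pulls dim signals together, 5 were higher (miR-96, miR-714, miR-494, miR-148a and miR-103) and 5 lower (miR-1224, miR-680, miR-370, miR-214 and miR-720), and the other miRNAs of the main count fell below 2-fold.

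**Figure D1:**
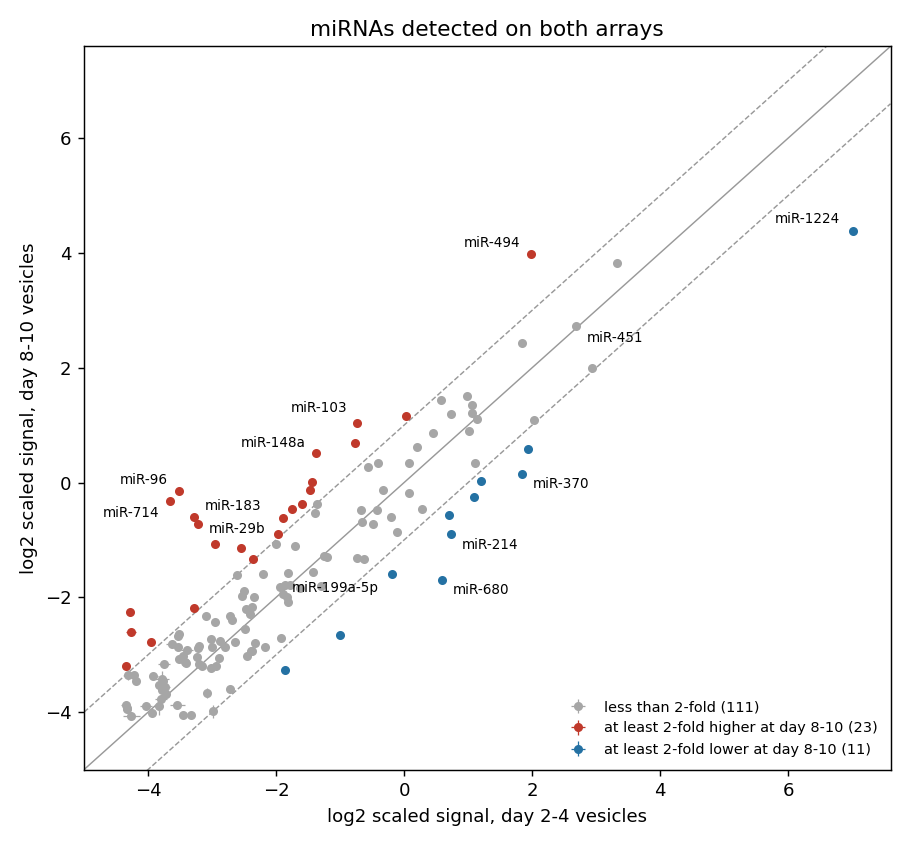
Log2 scaled signal of the 145 miRNAs detected on both arrays, day 2-4 vesicles on the horizontal and day 8-10 vesicles on the vertical axis. Each point is 1 miRNA with the standard error over spots, the solid line marks equal signal and the dashed lines a 2-fold difference, and miR-96 lies farthest above the lines while miR-1224 lies farthest below.

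Large gains in late vesicles included members of the miR-183/96/182 cluster and of the miR-29 family. miR-96 was 10.4-fold higher at day 8-10 (log2 difference 3.37, spot SE 0.051) and miR-183 was 6.40-fold higher (2.68, spot SE 0.048). miR-182, the remaining member of that cluster, was not well above background at day 2-4 and was at least 4.48-fold higher at day 8-10 in the main setting, as a mean over probes with log2 differences of 0.43 and 3.89. In the files these miRNAs lie on chromosome 6, miR-182 at 30115962 to 30115977, miR-96 at 30119506 to 30119526 and miR-183 at 30119711 to 30119728, with the genome build not given in the sources used here. The RefSeq names table of GRCm38.p6 places all of them inside the long noncoding RNA gene Mirc35hg. The 3 members of the miR-29 family, known for targeting transcripts of the extracellular matrix, had a median log2 difference of 1.87, at percentile 94.7 of random lists matched on signal. Of these, miR-29b was 5.67-fold higher and miR-29c 3.67-fold higher, whereas miR-29a, at 1.81-fold, stayed below 2-fold. The value of miR-29b rests on 1 of its 2 probes, the other being detected on neither array. With normexp background correction, miR-183 (log2 difference 0.96), miR-182 (0.63), miR-29b (0.88) and miR-29c (0.65) fell below 2-fold. The log2 difference of miR-96 was then 1.24. miR-29b and miR-29c differ little in sequence, and their probes may share signal. miR-148a was 3.72-fold higher (log2 difference 1.90, spot SE 0.014). Other gains were those of miR-714 (10.1-fold), miR-706 (4.07-fold) and miR-494 (4.02-fold). With normexp the log2 differences were 1.10 for miR-148a, 1.61 for miR-714, 0.58 for miR-706 and 1.81 for miR-494.

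miRNAs linked to adipocyte differentiation gave higher signals in the late vesicles as a group. The list of miRNAs known to rise in or to promote adipogenesis had 18 detected members, of which 9 were at least 2-fold higher at day 8-10, none was at least 2-fold lower and 9 stayed within 2-fold. Its median log2 difference was 1.01, at percentile 99.9 among 10000 random lists of the same size matched on signal, which describes these arrays and is not a test. Besides miR-148a, the higher members were miR-103 (3.44-fold), miR-107 (2.76-fold), miR-365 (2.71-fold), miR-210 (2.66-fold, known to be induced by hypoxia), miR-378 (2.53-fold), miR-30e (2.13-fold), miR-193 (2.11-fold) and miR-30c (2.04-fold). The value of miR-30c rests on 1 of its 2 probes. In the GRCm38.p6 table, the genes of miR-103 lie within Pank3 and Pank2, that of miR-107 within Pank1, and that of miR-378 within Ppargc1b, a coactivator of mitochondrial genes. Members within 2-fold included miR-26b (log2 difference 0.99), miR-30a (0.85), miR-143 (0.77), miR-34a (0.22), miR-21 (0.16), miR-193b (-0.034), miR-26a (-0.048), miR-30d (-0.097) and miR-146b (-0.15). The signs of miR-21, miR-34a, miR-30d and miR-146b turned under at least 1 other scaling or background correction. The list median was lowest, at 0.38, with normexp background correction. miR-103 with miR-107, and the miR-30, miR-26 and miR-193 members, are near-identical pairs or sets whose probes may share signal. With 1 member kept for each such set, the list stood at percentile 96.1, and with normexp background correction at percentile 96.2.

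Among miRNAs known to fall in adipogenesis or to repress it, the 7 detected on both arrays differed by less than 2-fold. Over the 9 members detected on either array, the median log2 difference was 0.20 at percentile 34.5, turning negative under 4 of 7 other scalings and background corrections. miR-27a and miR-27b, which repress the adipogenic regulator Pparg, had log2 differences of 0.26 and 0.85. miR-130a, which also targets Pparg, had 0.46, miR-31 had 0.26, miR-224 had 0.20, miR-125b-5p had -0.25 and miR-221 had -0.57. miR-155 was not well above background at day 8-10 and was at least 1.26-fold higher at day 2-4, and miR-138 was detected at day 2-4 without a usable bound. The signs of miR-27a, miR-130a, miR-31 and miR-224 turned under at least 1 other scaling.

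The largest losses in late vesicles included miRNAs of fibroblast-like cells. miR-214 was 3.09-fold lower at day 8-10 (log2 difference -1.63, spot SE 0.025) and miR-199a-5p 2.64-fold lower (-1.40, spot SE 0.045). The files place miR-199a-5p on chromosome 1 at 164147980 to 164147997 and miR-214 at 164153578 to 164153590, and the GRCm38.p6 table has Mir214 and Mir199a-2 within the noncoding gene Dnm3os. miR-199b was 1.93-fold lower, less than 2-fold. The files place this entry on chromosome 1 at 164148017 to 164148035, beside miR-199a-5p, but miR-199b* on chromosome 2. The entry shares its sequence with miR-199a-3p, so its loss may not be separate from that of miR-199a-5p. The list of fibroblast and mesenchymal miRNAs as a whole had 14 detected members, and of the 13 detected on both arrays 2 were at least 2-fold lower and none at least 2-fold higher. Its median log2 difference of -0.11 lay at percentile 7.06 and turned positive with normexp background correction. miR-22, a member of this list, had a log2 difference of 0.59.

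Other losses concerned miR-1224, which was 6.16-fold lower at day 8-10 (log2 difference -2.62, spot SE 0.018). It made up 77.7% of the summed mouse miRNA signal at day 2-4 and 36.7% at day 8-10. Signals of different probes are not amounts, so these are shares of signal and not of miRNA. miR-1224 is on the list of GC-rich or fragment entries. The files place miR-1224 on chromosome 16 at 20604537 to 20604545, and its gene lies within Vwa5b2 in the GRCm38.p6 table. miR-680 was 4.88-fold lower, miR-370 3.24-fold lower, miR-762 3.12-fold lower, miR-710 2.64-fold lower and miR-720 2.54-fold lower. With normexp the log2 differences were -1.25 (miR-680), -1.34 (miR-370) and -1.08 (miR-720), while miR-762 (-0.71) and miR-710 (-0.28) fell below 2-fold. For miR-762 the probes of the entry moved in opposite directions, with log2 differences from -2.75 to 0.31, and the same entry-level disagreement in size was seen for miR-706 (0.77 to 3.28) and miR-714 (0.65 to 5.02).

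Further miRNAs crossed the detection limit between the windows. For these, a lower bound that holds for the main background correction and scaling was taken as the signal on the array that detected the miRNA over the higher of the other array's lowest detected probe and the miRNA's own signal there. In all, 21 miRNAs were detected only at day 8-10, 8 of them at least 2-fold higher by this bound. Among them miR-690 was at least 18.5-fold higher, miR-681 at least 5.12-fold higher and miR-805 at least 4.12-fold higher. With normexp background correction their log2 differences were smaller than these bounds, at 1.31, 0.53 and 0.39. miR-690 is on the list of GC-rich or fragment entries. The given position of miR-805 is on the mitochondrial chromosome, and no miRNA gene was found for it among the RefSeq names of GRCm38.p6. None was found there for miR-714, miR-720 or miR-689 either, and the files give no position for miR-714. Another 11 miRNAs were detected only at day 2-4, and 1 of these, miR-503, was at least 2-fold higher there, by at least 4.28-fold, but with a log2 difference of -0.35 with normexp. The bound of miR-503 rests on 1 of its 2 probes and that of miR-805 on 1 of its 4 probes. Smaller bounds applied to miR-339-3p, at least 1.24-fold higher at day 2-4, and to miR-450a-5p, at least 1.09-fold higher. The signs of both, and that of miR-155, turned with normexp background correction.

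The let-7 family, which restrains proliferation in differentiated cells, had its 9 members detected on both arrays. let-7b was 2.17-fold higher at day 8-10 and miR-98 2.25-fold higher, and the family median log2 difference of 0.52 lay at percentile 88.8 and was 0.012 with the 75th percentile taken over all probes. Other members had log2 differences of 0.83 (let-7i), 0.75 (let-7g), 0.52 (let-7c), 0.43 (let-7f), 0.20 (let-7d), -0.040 (let-7a) and -0.39 (let-7e). The signs of let-7f and let-7d turned under at least 1 other scaling. let-7 members differ by few bases and may share signal.

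Members of growth-associated families that were detected on both arrays differed by less than 2-fold, except miR-322. For miR-17-92 and its paralog clusters this held for 7 members, and the 8 detected on either array had a median of 0.36 at percentile 51.5 that turned negative under 2 other normalizations. Within it, miR-106b had a log2 difference of 0.92, miR-19b 0.62 and miR-92a -0.51, while miR-19a was detected only at day 8-10, at least 1.80-fold higher. In the miR-15/16 family, which acts on the cell cycle, miR-322 was 2.25-fold lower at day 8-10, and miR-15a (0.99) and miR-497 (0.96) lay just under 2-fold. miR-195 was detected only at day 8-10, at least 1.52-fold higher, and the 6 members had a median of 0.40 at percentile 57.8, negative under 1 other scaling. The 5 members of the miR-23/27/24 clusters, with miR-24 at 0.41 (-0.10 with the 75th percentile taken over all probes) and miR-23a at -0.12, had a median of 0.26 at percentile 48.9, negative under 2 other scalings. The imprinted Dlk1-Dio3 cluster had 4 of its 59 array entries detected, with miR-494 higher, miR-370 lower, miR-134 at -0.77 and miR-770-3p at 0.49, the last at -0.023 with the 75th percentile taken over all probes. Its median of -0.14 lay at percentile 16.1 and turned positive with normexp and with the scanner software's gene signal. The 8 detected members of the Sfmbt2 cluster, among them miR-297a (0.37), miR-466f-5p (0.36), miR-467c (0.31) and miR-669b (0.30), had a median of 0.30 at percentile 50.3, negative under 2 other normalizations, and each of these named members turned negative under at least 1 of them.

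**Figure D2:**
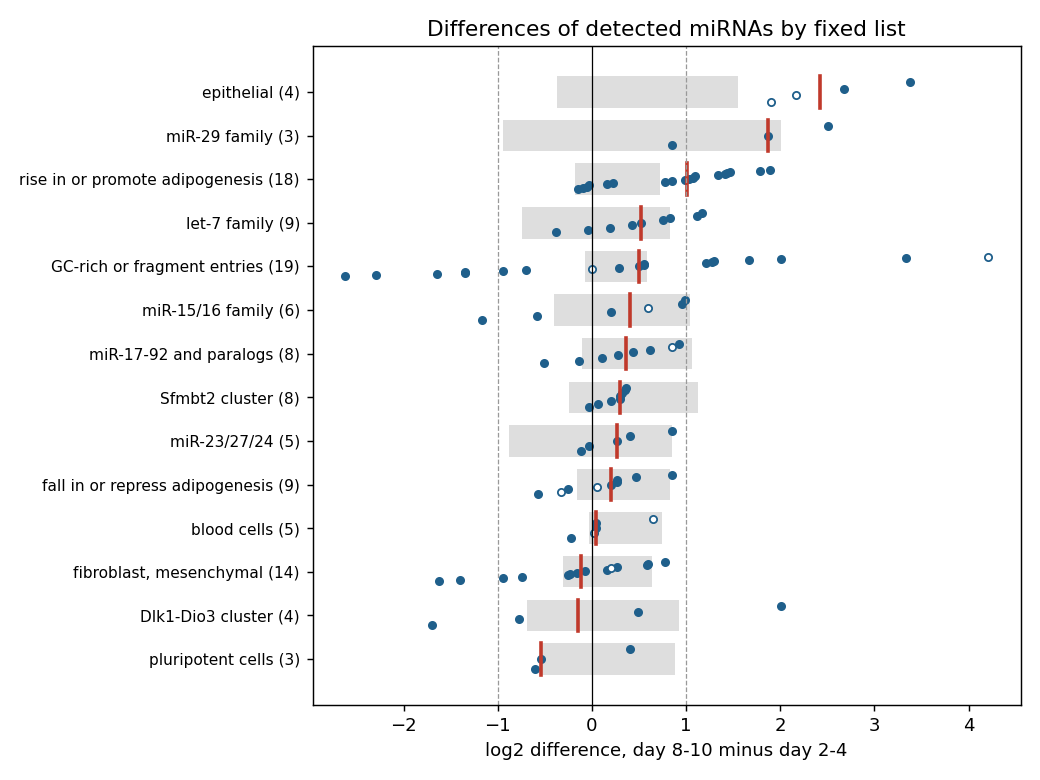
Log2 difference, day 8-10 minus day 2-4, of every detected member of each fixed list with at least 3 detected members. Filled points were detected on both arrays and open points on 1. Red bars are list medians, grey boxes hold the central 95% of medians of random lists matched on signal, and dashed lines mark 2-fold. The medians of the epithelial list (2.42) and of the miRNAs that rise in or promote adipogenesis (1.01) lie above their boxes. All detected members of the epithelial list but miR-205 belong to 1 cluster.

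Most markers of other cell types were undetected, with blood-cell miRNAs the exception at 5 of 9. Most mouse miRNAs of the array were undetected too, at 390 of 567. The undetected markers therefore do not show that RNA of other cell types was absent. None of the 7 muscle miRNAs and neither of the 2 endothelial miRNAs was detected. Of the 8 neural miRNAs, miR-128 alone was detected, with a log2 difference of -0.33 that turned to 0.030 with normexp. Of the 5 liver and pancreas miRNAs, miR-192 was 2.20-fold higher at day 8-10, and miR-194 was detected only then, at least 1.46-fold higher. Each value rests on 1 of 2 probes. The day 2-4 signal of miR-192, at 5.31, lay near the floor of 4.86, and its log2 difference with normexp was 0.22. The epithelial list had 4 of 10 members detected, with miR-96 and miR-183 higher and miR-182 and miR-205 detected only at day 8-10, miR-205 at least 3.74-fold higher in the main setting but with a log2 difference of 0.41 with normexp. The list median of 2.42 lay at percentile 99.95, and with normexp it was 0.79. All detected members but miR-205 belong to 1 cluster, which the random lists do not take into account, so the percentile largely restates the gain of that cluster. Among the 9 blood-cell miRNAs, which serum also carries, the erythroid miR-451 had a log2 difference of 0.043, miR-486 of 0.046 and the myeloid miR-223 of -0.22. Each of these signs turned under at least 1 other scaling or background correction. miR-144 was detected only at day 8-10, at least 1.57-fold higher. The 5 detected blood members had a median of 0.043 at percentile 10.7, of the opposite sign under 6 of 7 other scalings and background corrections. Of the pluripotent-cell miRNAs, 3 of 16 were detected, miR-290-5p at -0.55, miR-292-5p at -0.60 and miR-294 at 0.41, with a median of -0.55 at percentile 3.46 that came to -0.0020 with normexp. The sign of miR-294 turned with the 75th percentile taken over all probes and with quantile normalization.

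Array entries that are GC-rich or may stem from fragments of other RNA classes moved in both directions. Of the 19 detected entries, 6 were at least 2-fold higher at day 8-10, miR-714 and miR-494 among them, and 5 were at least 2-fold lower, miR-1224 and miR-680 among them. miR-574-5p had a log2 difference of 0.29, and of -0.22 with the 75th percentile taken over all probes. The median of 0.50 lay at percentile 91.4 and was negative with the 75th percentile taken over all probes.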

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

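The signals in this part come from control and viral probes, which were looked at only after the miRNA results were seen, and no explanation was tested for them. Each is the mean intensity at day 8-10 over that at day 2-4, without scaling, for a probe well above background on both arrays. The control probes hur_1, hur_2, hur_4 and hur_6, whose targets the files do not name, were brighter at day 8-10 by 6.23, 4.48, 9.89 and 4.25 times, over 20 spots each, while hur_5 was not well above background. The corner control miRNABrightCorner30 was 3.89 times as bright. The control probe mr_1 went the other way, at 0.776 times. The probe of mghv-miR-M1-2, a miRNA of murine gammaherpesvirus, gave a near-equal signal on both arrays, at 0.995 times, with 18 of 20 spots well above background at day 2-4 and 16 at day 8-10.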

How the results depend on the processing

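The common floor, the median difference set to 0, the run without GC-rich entries and the run with 1 member per near-identical set were chosen only after the results were seen. Of all values of named miRNAs under alternatives, 526 moved by more than the spot SD of the difference, combined over both arrays, and 475 did not. The 28 named 2-fold miRNAs kept their sign in each of their 308 values. Part of this was fixed in advance, since the series value table held the main input. Several scalings also moved every difference by 1 constant smaller than 2-fold. Scaling moved the median of all miRNAs by -0.51 (75th percentile over all probes), -0.32 (quantile), -0.27 (median), -0.19 (gene signal), -0.20 (median set to 0), -0.19 (no scaling) and -0.084 (normexp). The share of higher among counted miRNAs, 67.6% in the main analysis, was then 25.6%, 42.4%, 45.7%, 52.8%, 53.1%, 53.1% and 50%. Counts of higher and lower miRNAs, 23 and 11, became 10 and 29 (75th percentile over all probes), 14 and 19 (quantile), 5 and 5 (normexp), 43 and 24 (1.5-fold) and 10 and 5 (3-fold). Lower miRNAs numbered 19 (median scaling), 17 (gene signal), 18 (any spot), 17 (gene flag) and 6 (without GC-rich entries), and miRNAs detected only at day 2-4 numbered 20 (any spot) instead of 11. The 11 lower miRNAs were kept under each scaling except normexp, which kept 5, and of the 23 higher ones normexp kept 5, the 75th percentile over all probes 10, quantile 14, median scaling 16, and no scaling, gene signal and median set to 0 kept 17 each. Apart from normexp, these scalings moved the differences downward as a whole. The contrast follows that direction and does not show that losses were firmer than gains. The list that rises in adipogenesis fell to 0.38 (percentile 96.2) with normexp and 0.81 (96.1) with 1 member per set. Outside the central 95% of random lists, unlike in the main analysis, were miR-29 with normexp (0.65), the brightest probe (1.84) and gene signal (1.66), pluripotent miRNAs with quantile (-0.92), outlier spots kept (-0.53), members detected on both arrays (-0.55) and the common floor (-0.55), and Dlk1-Dio3 without 1 member (-0.77) or GC-rich entries (-0.77). The cause was not tested, except that thresholds and removed entries act by construction. The normexp offset of 50 also acts by construction, shrinking differences between dim signals. The other 275 values for counts, lists and correlations stayed in range. No probe was saturated, so leaving such probes out gave no value. Signals near background limit the small differences.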

Other observations

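The tests in this part were chosen only after the result was seen, except the one on dim signal, while the other normalizations and normexp, whose values some of them read, were fixed before the data were examined. Of neighbouring miRNAs on the X chromosome, picked after their values were seen, some were lower in late vesicles and some were not. miR-322, at 50407483 to 50407504 in the files, was 2.25-fold lower at day 8-10. miR-503, at 50407204 to 50407219, and miR-351, at 50406492 to 50406504, were detected only at day 2-4, by at least 4.28-fold and at least 1.05-fold in the main setting, and miR-503 had a log2 difference of -0.35 with normexp. The GRCm38.p6 table places all of them within the noncoding gene C430049B03Rik. Nearby on the same chromosome, miR-542-5p had a log2 difference of -0.068 and miR-450a-3p of 0.21, while miR-450a-5p was detected only at day 2-4, by at least 1.09-fold.

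The miRNAs that rise in or promote adipogenesis were higher in late vesicles as a list. Less RNA from outside the cultured cells at day 8-10 would by itself raise fibroblast and mesenchymal miRNAs alike. The 12 detected ones outside the list had a median log2 difference of -0.19, more than 1 SD of the list (0.68) below the list's median of 1.01. These miRNAs could also fall as the preadipocytes differentiate, so their lower median does not decide about RNA from outside the cells. Background correction could still account for part of the position, since the lowest percentile under 3 other normalizations was 96.2, as could shared signal between near-identical members, with percentile 96.1 when 1 member was kept for each set. Days of differentiation remain open and cannot be told apart from preparation with 1 array per group.

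miR-96, miR-183 and miR-182 were higher in late vesicles, and a candidate source is RNA of epithelial cells, which carry this cluster and miR-205. miR-205 goes with it, detected only at day 8-10 and at least 3.74-fold higher in the main setting, with a log2 difference of 0.41 with normexp. Against it, 0 of the 5 members of the miR-200 family, abundant in epithelium, were detected at day 8-10. Background correction or normalization could set the size of the difference, since the lowest value of miR-96 or miR-183 under the alternatives was 0.96, with normexp. The normexp offset of 50 shrinks differences between dim signals by construction. No biological explanation other than the time window is given by the design, and with 1 array per group it was not tested.

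Probes of the same GC-rich or fragment entry moved apart. Their mean absolute log2 difference was 0.42 over 16 entries, against 0.11 over 85 other miRNAs with several probes. Neither the mean signal of an entry nor its number of probes accounted for it when matched alone. The excess was 0.32 over other miRNAs matched on mean signal and 0.26 over those with as many probes. Both lay beyond the central 95% of random choices. Signal was matched on the mean of an entry and not on each probe, and never together with the number of probes. Dim probes within an entry are therefore not excluded. Whether these entries read fragments of other RNAs stays open, because no value here is specific to fragments. No biological explanation was tested for this pattern.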
